A study of Homo sapiens with 9 samples.

How the data were processed

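RNA from HEK293 cells, a human embryonic kidney cell line, was measured on 9 single-colour Affymetrix arrays after biotin labelling, per the labels' protocols. The labels' protocols give column extraction of RNA with DNase digestion. The labels place 3 arrays in each of 3 groups. The mock group is cells labelled as naive or mock control, without cumate, the GPR39 group is cells labelled as overexpressing GPR39 with 0.03 mg/mL cumate, and the agonist group is cells labelled as overexpressing GPR39 with 1 uM TC-G-1008. The labels do not say whether the agonist group also received cumate, and they give no exposure time. They call the replicates biological without saying whether each was a separate culture, so p-values measure the spread between these arrays. No group is labelled with cumate or agonist but without the receptor. In GPR39 against mock the receptor and cumate therefore cannot be separated. Both groups of agonist against GPR39 carry the receptor label, and there the agonist cannot be separated from a possible lack of cumate.

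The deposited values are log2 signals per probe set, judged from the values, which run from 0.717 to 13.4977 with similar quantiles in all 9 columns. The values were made with MAS5, per the submitters' processing notes, which name no other tool. The background correction, the normalization between arrays, the log step and the software version are not given in the sources used here. MAS5 commonly gives linear signals, so how the log2 values were reached stays unknown. Between arrays, up to 6.49% of the values in a pair were exactly equal. What made these ties was not tested, so a normalization between arrays before deposit stays open. MAS5 as the only step therefore rests on the processing notes alone. The design written before the data were examined foresaw linear values with a pseudocount of 16, or log2 values used as they are, and the latter was followed with no added pseudocount.

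The table holds 53617 probe sets. The annotation table of the array platform gives 1 gene symbol for 16098 of them, several for 0 and none for 37519, and symbols were looked up again by Entrez identifier in RefSeq genes of assembly GRCh38.p14, which found all 16098. Unnamed probe sets were tested and counted but not named. Many well-known genes have no named probe set here, and no result is given for them. Control probe sets could not be told from others by their identifiers and stayed in. Of all rows, 1318 repeat an earlier row exactly. Array data give no read depth, and the number of arrays limits the precision.

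Probe sets above the 40th percentile of their array in at least 3 of the 9 arrays were tested, which left 33376 probe sets, 12827 of them named, for 11916 genes. All 9 arrays were fitted together in limma 3.58.1 in R 4.3.3 with lmFit and eBayes, with 6 residual and 2.12 prior degrees of freedom. Tests were two-sided with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. Errors given after a log2 change are the standard errors of that fit, and errors given after a level are SDs over 3 arrays. Where the change of a named gene passed and its lower group had arrays at or below the 40th percentile, it was written as "at least", with that percentile (2.63 to 2.70) in place of dimmer values. That rule was set after the data were examined. Fitted values of such genes appear in the plots.

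Before the data were examined, 30 gene lists holding 568 genes were fixed, of which 330 genes have a named probe set. Some genes, such as ATF3, are members of several lists, so calls of different lists are not independent of each other. Lists with at least 4 tested members were tested with camera in limma at a preset correlation of 0.01, 1 probe set per gene, with adjustment over the 27 lists tested. The fibroblast and hepatocyte markers had too few tested members, 1 and 3, and the zinc transporter list had none named. Genes named in the text follow a rule fixed at the same time. It takes GPR39, then per comparison the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose arrays do not overlap and whose mean in the higher group is above 4.60, the median of all tested values. It adds up to 4 members with the smallest p of each list past the threshold, of each list with at least 2 members past it, and of 6 signalling lists in any case.

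The scripts were tested on simulated data with the real means and spreads, in 10 draws of 200 changed probe sets among 33376 per comparison. For GPR39 against mock, 38.8% of 1.5-fold, 70.0% of 2-fold and 93.9% of 4-fold changes were recovered. For agonist against GPR39 the shares were 38.4%, 68.2% and 90.8%, and for agonist against mock 39.0%, 70.4% and 93.0%. A random list of 20 probe sets shifted by 0.3 was called by camera in each comparison and none of the others was. Probe sets were drawn independently of each other, so this cannot show how camera behaves on lists of correlated genes. No recovered change had the wrong sign, and the share of false calls was 5.80%, 4.72% and 6.33% in the same order.

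Alternatives planned before the data were examined were added pseudocounts of 1 and 64 on the linear scale, quantile normalization, centring on the 75th percentile, no filter, a filter at the 60th percentile, fits of the compared arrays alone, eBayes with trend and robust, the replicate number as a block, 1 probe set per gene, array weights, stricter thresholds, leaving out each array, and for lists an estimated correlation, fry and the mean of a gene's probe sets. A pseudocount of 16, repeated rows counted once, centring on probe sets above 6, cyclic loess and tests of families of genes that share a symbol stem were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.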

Results

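The transcriptome of HEK293 cells was measured in mock control cells, in cells labelled as overexpressing GPR39 and treated with cumate, and in cells labelled as overexpressing GPR39 and treated with TC-G-1008, with 3 arrays in each group. GPR39 is a zinc-sensing G protein-coupled receptor, cumate is a small molecule used to switch on engineered genes, and TC-G-1008 is a synthetic GPR39 agonist. Array medians over all probe sets lay between 3.13 and 3.22 on the log2 scale. Correlations within a group, across probe sets, ran from 0.977 to 0.987 for mock, from 0.986 to 0.988 for GPR39 and from 0.983 to 0.985 for the agonist group. Mock replicate 1 correlated more with the GPR39 arrays (mean 0.984) than with the other mock arrays (mean 0.979). On the second principal component of the arrays, with 20.4% of the variance, it lay at 22.0, near the GPR39 arrays (24.2 to 27.3). Mock replicates 2 and 3 (-22.9 and -38.7) and the agonist arrays (-23.3 to -5.2) lay on the other side. That axis therefore also separates the GPR39 from the agonist arrays, and what it reflects was not tested.

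The GPR39 transcript was examined first as a check on the labels. Its 1 probe set read 2.47 ± 0.07 (SD, n = 3) in mock, 2.58 ± 0.04 in the GPR39 arrays and 2.58 ± 0.11 in the agonist arrays, all between 2.43 and 2.65 and too dim to pass the filter. The log2 change from mock to GPR39 was 0.11 ± 0.08, with a 95% interval from -0.07 to 0.29. A rise in GPR39 was therefore not measured in the arrays labelled as overexpressing it. A probe set that lies outside the introduced sequence checks nothing, and where its probes lie is not given in the sources used here. The groups are named below by their labels.

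**Figure D1:**
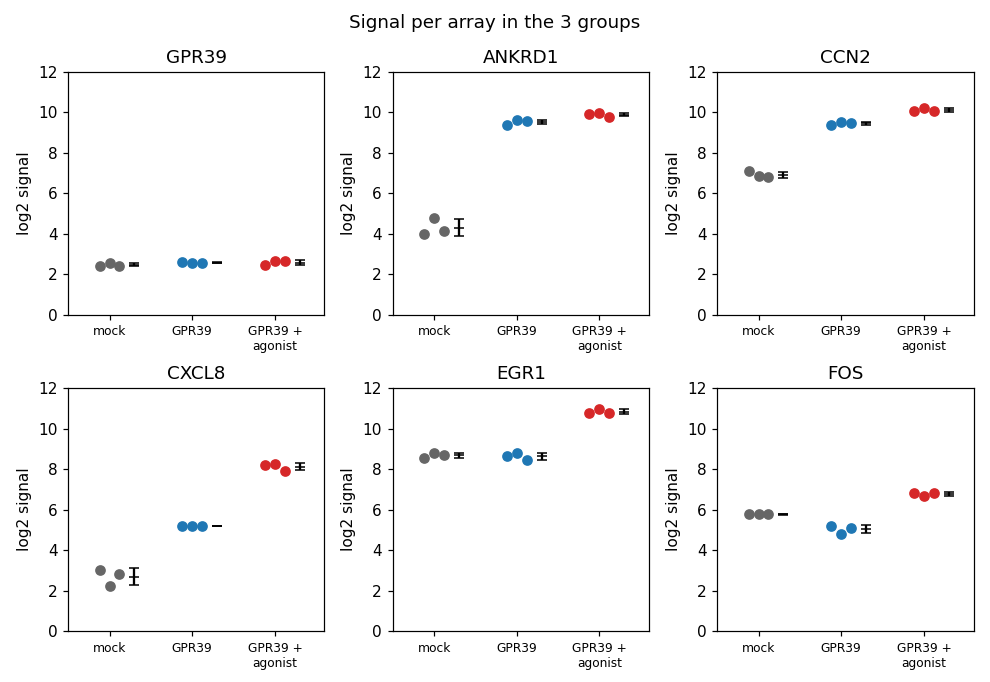
Log2 signal of 6 genes in each of the 9 arrays, with points for arrays and the mean ± SD of 3 arrays beside them. GPR39 stays between 2.43 and 2.65 in every array, while ANKRD1 rises by 5.22 in the GPR39 arrays and EGR1 by 2.19 from the GPR39 to the agonist arrays.

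Cells of the GPR39 group were compared with mock to ask what the receptor label with cumate goes with. ANKRD1, a nuclear ankyrin repeat protein and a common YAP target, rose 37.3-fold, from 4.31 ± 0.41 to 9.52 ± 0.12 (SD, n = 3; log2 change 5.22 ± 0.18). CCN2, which encodes connective tissue growth factor, rose by 2.54 ± 0.09. The chemokine genes CCL2 and CCL20 rose by 1.99 ± 0.17 and 1.77 ± 0.17. A further chemokine gene, CXCL8, rose by at least 2.35, from a mock mean of 2.69 with 1 of 3 arrays at or below the 40th percentile to 5.18. The collagenase gene MMP13 rose by 2.20 ± 0.12. GEM, a small GTP-binding protein gene, rose by 2.38 ± 0.14, MYOF by 2.05 ± 0.07, CD70 from 5.27 ± 0.25 to 7.27 ± 0.15 (SD, n = 3), GLIPR1 by 1.99 ± 0.09, the AP-1 subunit gene FOSL1 by 1.81 ± 0.14 and the hyaluronan receptor gene CD44 by 1.75 ± 0.08. AMOT, which encodes the YAP-binding protein angiomotin, changed by -1.41 ± 0.10, the developmental transcription factor genes HOXA2 and HOXB5 by -1.39 ± 0.09 and -0.92 ± 0.08, and IGFBP5 by -1.37 ± 0.10. Falls also passed for the matrix proteoglycan gene VCAN at -1.19 ± 0.19, for EBF2 at -1.16 ± 0.17, ZNF221 at -1.10 ± 0.11, the endocytic receptor gene LRP2 at -1.03 ± 0.16, IRS4 at -1.03 ± 0.14, KBTBD7 at -1.02 ± 0.11 and the guidance gene SLIT2 at -0.98 ± 0.13. NRP1, a semaphorin receptor gene, changed by -1.002 ± 0.09. The largest adjusted p among these 24 genes was 0.028, for VCAN.

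Among the lists, 7 of 16 ERK output and feedback genes rose and none fell, with a median change of 0.50 (camera adjusted p = 3.61e-10, and adjusted p = 0.0137 with an estimated correlation). IER3, EPHA2 and DUSP4 rose by 1.46, 1.03 and 1.14. Of 12 NF-kB and inflammatory genes 6 rose, among them NFKB1 by 0.86 and NFKB2 by 0.94 (adjusted p = 3.61e-10, and adjusted p = 0.0111 with an estimated correlation). Of 15 SRF and YAP target genes 4 rose, ANKRD1, CCN2, CNN2 by 0.68 and AMOTL2 by 0.75 (adjusted p = 4.06e-10, and adjusted p = 0.0154 with an estimated correlation). Of 21 immediate-early genes 6 rose, including JUNB by 1.19 and ATF3 by 1.39, and FOS changed by -0.74 ± 0.11, with its other probe set at -0.06 and not past the threshold (adjusted p = 3.35e-08, and adjusted p = 0.0111 with an estimated correlation). Adjusted over the list alone, 10, 7, 11 and 11 members rose in these 4 lists, and 1 immediate-early gene fell.

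The other 9 lists past the threshold lost it with an estimated correlation. For the CREB, adhesion, fatty acid and leukocyte lists the estimated correlation, 0.007, -0.018, -0.023 and -0.078, was below the preset 0.01. A higher correlation between members therefore cannot be the reason in those lists, and what else differs between the 2 forms of the test was not examined. Calcium and NFAT targets had 3 of 9 members higher and 1 lower, with RCAN1 at 1.12 and LIF at 0.61 (adjusted p = 0.0876 with an estimated correlation). Adhesion genes had 3 of 15 higher, CD44, THBS1 at 1.46 and CLDN1 at 0.86 (adjusted p = 0.0880). ER chaperone genes had 1 of 8 higher, XBP1 at 0.56 (adjusted p = 0.114), ATF4 and amino-acid response genes 1 of 16, ATF3 (adjusted p = 0.262), and fatty acid synthesis genes 1 of 10 lower, SCD at -0.41 (adjusted p = 0.114). No single member passed in the cAMP and CREB list (adjusted p = 0.104), the heat-shock list (adjusted p = 0.338) or the cholesterol list, whose shift was downward (adjusted p = 0.0880). The leukocyte marker list of 4 genes moved up (adjusted p = 0.114), with 1 member past the threshold, the lysosomal glycoprotein gene CD68 at 0.90 ± 0.12, while TYROBP, LAPTM5 and CD14 had mock means between 2.76 and 3.10. Adjusted over the list alone, these lists had 5 higher and 1 lower among calcium targets, 6 and 2 among adhesion genes, 5 and 1 among ATF4 genes, 0 and 3 among fatty acid genes, and at most 2 in any direction in the rest. The metallothionein genes MT1X, MT2A, MT1F and MT1E had log2 changes of -0.35, 0.10, 0.07 and 0.09, none past the threshold. The other 14 lists did not pass, with adjusted p between 0.152 and 0.894. Among them the median, mean and test differed in sign for the mitosis, neuronal, interferon, metallothionein and p53 lists. In the TGF-beta and BMP list the antagonist gene NOG, named here because it was the 1 member past the threshold, rose by 0.54.

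In all, 391 of 33376 probe sets passed, 250 higher and 141 lower, for 124 and 72 named genes. Centring on the 75th percentile gave 74.7% higher against 63.9% as deposited. Without mock replicate 1 the count was 1324, with 905 lower and 419 higher, and 371 of the 391 remained. Without mock replicates 2 and 3 it was 137 and 193, and without GPR39 replicates 1, 2 and 3 it was 150, 115 and 108, with the calls of VCAN, EBF2, LRP2, IRS4, SLIT2, FOS, CNN2, AMOTL2, CLDN1, LIF, XBP1, SCD and CD68 each lost without at least 1 of these arrays.

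The agonist arrays were compared with the GPR39 arrays to ask what TC-G-1008 goes with in cells carrying the receptor label. The labels give cumate for the GPR39 arrays and do not give it for the agonist arrays. MMP10, a stromelysin gene, rose by 4.42 ± 0.09, and RRAD, which encodes a small GTP-binding protein, by at least 3.75, from a GPR39 mean of 2.59 with 1 of 3 arrays at or below the 40th percentile to 6.499. The activity-regulated genes ARC, FOSB and EGR1 rose by 2.91 ± 0.11, 2.66 ± 0.12 and 2.19 ± 0.12. CXCL8 and CCL20, already higher in the GPR39 arrays than in mock, rose by a further 2.95 ± 0.19 and 2.46 ± 0.17. The Notch feedback gene NRARP rose by 2.36 ± 0.11. TM4SF1 and the anti-apoptotic gene BCL2A1 rose by at least 2.40 and 2.35, to 5.04 and 5.12 from GPR39 means of 2.34 and 2.66, with 3 and 1 of 3 arrays at or below the 40th percentile. USP17L12 and USP17L9P carry identical values, 2.27 ± 0.09, and cannot be separated. Falls were smaller. LINC02893 changed by -1.67 ± 0.21, DUSP19 by -1.50 ± 0.13, ZNF449 by -1.48 ± 0.07, the mitochondrial protease gene OMA1 by -1.32 ± 0.17 and GIN1 by -1.25 ± 0.15. MANSC1, TMT1A, NUDT12, CTSO, SERTAD4, C2orf74-DT and GPX8 changed by between -1.21 and -1.17. The largest adjusted p among these 24 genes was 0.0095, for CTSO.

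Of 21 immediate-early genes 15 rose and none fell, including DUSP1 by 1.34, with a median of 0.59 (camera adjusted p = 4.87e-18, and adjusted p = 0.00165 with an estimated correlation). Of 16 ERK output genes 9 rose and 1 fell, with EPHA2 at 1.03, CCND1 at 0.62 and SPRY2 at 0.56 (adjusted p = 1.48e-07, and adjusted p = 0.0316 with an estimated correlation). Of 8 ER chaperone genes 4 rose, SEL1L by 0.82, HYOU1 by 0.69, XBP1 by 0.67 and MANF by 0.86 (adjusted p = 1.35e-06, and adjusted p = 0.0316 with an estimated correlation). Adjusted over the list alone, 19, 11 and 5 members rose in these lists, with 1 immediate-early and 2 ERK genes lower.

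Another 10 lists passed at the preset correlation and lost the call with an estimated one. The estimated correlations of the CREB, fatty acid and TGF-beta lists, 0.007, -0.023 and -0.051, were again below 0.01 and cannot be the reason there. ATF4 and amino-acid response genes had 8 of 16 higher, with CTH at 1.29, STC2 at 0.86, ASNS at 0.78 and ATF4 itself at 0.57 (adjusted p = 0.0579 with an estimated correlation). NF-kB genes had 4 of 12 higher (adjusted p = 0.0579). The cAMP and CREB targets had 3 of 10 higher, FOSB, SIK1 at 1.11 and PCK1 at 0.66 (adjusted p = 0.0556). Hypoxia and glycolysis genes had 5 of 13 higher, among them NDRG1 at 1.20, ANKRD37 at 0.81 and VEGFA at 0.49 (adjusted p = 0.0591). Calcium and NFAT targets had 4 of 9 higher and 2 lower, with IL11 at 2.17 and EGR3 at 1.08 (adjusted p = 0.0742). Mitotic genes had 6 of 17 lower, with HMMR at -0.71, KIF20A at -0.69 and PLK1 at -0.40 (adjusted p = 0.210). Fatty acid synthesis genes had 5 of 10 lower, including the elongase gene ELOVL6 at -0.83 and the desaturase gene SCD at -0.46, and TGF-beta and BMP genes had 3 of 7 lower, NOG at -0.82, SMAD7 at -0.77 and BMP4 at -0.72 (adjusted p = 0.151 for each). DNA replication genes had 2 higher and 1 lower of 19, with RRM2 at 0.63 (adjusted p = 0.385), and no ribosomal protein gene of 23 passed by itself (adjusted p = 0.353). Adjusted over the list alone, 10 ATF4, 6 NF-kB, 5 CREB, 7 hypoxia and 6 calcium genes were higher, and 2 NF-kB, 2 calcium and 11 mitotic genes were lower. The same adjustment gave 5 fatty acid and 3 TGF-beta genes lower, 4 replication genes higher and 1 lower, and no ribosomal gene.

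Several lists that did not pass held changed members in this step. The SRF and YAP, apoptosis and Wnt lists had medians, means and tests that differed in sign. SRF and YAP targets, with a median of -0.04, had CCN2 at 0.66 but ZYX at -0.43 and AJUBA at -0.58. The metallothionein gene MT2A rose by 0.65 ± 0.10 and MT1F changed by -0.80 ± 0.16. Heat-shock genes had 4 of 11 lower and 0 higher. The chaperone genes HSPA1A and HSPA1B, near-identical copies that arrays separate poorly, changed by -0.46 and -0.45. Among apoptosis regulators PMAIP1 and BCL2L11 rose by 0.81 and 0.44, and BCL2 and BCL2L1 changed by -0.73 and -0.67. Cholesterol genes had 3 of 16 higher and 4 lower, or 3 and 9 adjusted over the list alone, with a median of -0.22. Of these genes INSIG1 and HMGCS1 rose by 1.08 and 0.46 while SQLE changed by -0.40. Of Wnt targets, DKK1 rose by at least 0.85, from 2.44 with all 3 GPR39 arrays at or below the 40th percentile to 3.49, and RNF43 and APCDD1 changed by -0.83 and -0.82. The p53 target SESN2 rose by 0.75 and BAX changed by -0.44. Adhesion genes had CD44 at 0.80, THBS1 at 0.84 and FN1 at 0.50 higher and the keratin gene KRT19 at -0.62 (list adjusted p = 0.144). The lists of G protein signalling, neuronal, interferon, NRF2, oxidative phosphorylation and leukocyte genes also did not pass, with adjusted p between 0.206 and 0.721.

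**Figure D2:**
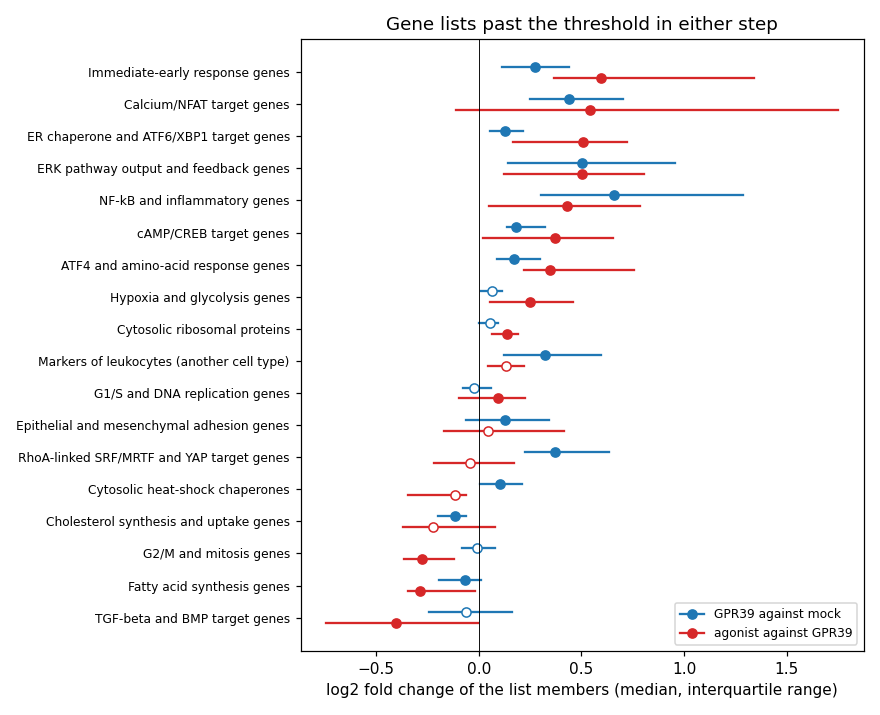
Median log2 fold change (points) and interquartile range (lines) over the tested members of each list past the threshold in either step, filled where camera at the preset correlation passed. Immediate-early genes have medians of 0.27 and 0.59, and SRF and YAP targets 0.37 and -0.04.

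In all, 3025 probe sets passed in this step, 1040 higher and 1985 lower, for 441 and 1162 named genes. Among changes of at least 1.5-fold the counts were 522 and 683, and above 2-fold 187 and 62. The 482 tested microRNA and -IT genes, a class chosen after seeing the data, had a median log2 change of 0.10 in this step, -0.03 in GPR39 against mock and 0.07 in agonist against mock. Without GPR39 replicates 1, 2 and 3 the count was 1589, 1537 and 1518. The calls of ACLY, AJUBA, APCDD1, BAX, BCL2L11, CCNB2, CDC6, DKK1, FADS2, FN1, GINS2, HK2, HMGCS1, HSPB1, KRT19, MT1F, PLK1, STARD4, VEGFA and ZYX were each lost without at least 1 array.

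Agonist and mock arrays were compared for the combined difference. ANKRD1 and MMP10 stood 5.59 ± 0.18 and 5.44 ± 0.09 higher. CXCL8, RRAD and TM4SF1, with 1, 2 and 3 of 3 mock arrays at or below the 40th percentile and mock means of 2.69, 2.497 and 2.18, stood at least 5.30, 3.81 and 2.39 higher, at 8.13, 6.499 and 5.04. CCL20 was higher by 4.24, GEM by 3.83, CCN2 by 3.19, the protease inhibitor gene TFPI2 by 3.10, MMP13 by 3.06, the cytokine gene IL11 by 2.87 and ARC by 2.87. AMOT and HOXA2 changed by -2.31 ± 0.10 and -1.92 ± 0.09, and the zinc finger gene ZNF449 from 6.07 ± 0.06 to 4.06 ± 0.08 (SD, n = 3). KLHL14, IGFBP5, LINC02893, TMT1A, NRP1, DUSP19, OMA1, TRIB2 and NUDT12 changed by between -1.82 and -1.60. The largest adjusted p among these 24 genes was 0.0012, for LINC02893. Of 21 immediate-early genes 19 rose, of 16 ERK genes 14, of 8 ER chaperone genes 7, of 12 NF-kB genes 8, of 9 calcium targets 7 and of 10 CREB targets 6, and these 6 lists passed with an estimated correlation too (adjusted p from 0.00129 to 0.0286). Adjusted over the list alone, 21, 14, 8, 10, 7 and 6 members rose in these lists, and 1 ERK gene and 1 calcium target fell, as over all probe sets. A further 10 lists passed at the preset correlation alone, although the adhesion, fatty acid, TGF-beta and leukocyte lists had estimated correlations below 0.01. ATF4 genes had 10 of 16 higher and 1 lower, and hypoxia genes 6 of 13 higher (adjusted p = 0.05002 with an estimated correlation for each). SRF and YAP targets had 6 of 15 higher (adjusted p = 0.0627 with an estimated correlation), fatty acid synthesis genes 6 of 10 lower and 1 higher (adjusted p = 0.0728), and adhesion genes 5 of 15 higher and 2 lower (adjusted p = 0.0803). TGF-beta and BMP genes had 5 of 7 lower (adjusted p = 0.0828), leukocyte markers CD68 alone higher (adjusted p = 0.118), and cholesterol genes 8 of 16 lower and 3 higher (adjusted p = 0.184). Mitotic genes had 7 of 17 lower (adjusted p = 0.228) and ribosomal protein genes 4 of 23 higher (adjusted p = 0.279). Adjusted over the list alone, the higher and lower members in these 10 lists were 12 and 1, 8 and 0, 7 and 1, 2 and 7, 7 and 3, 0 and 5, 2 and 0, 3 and 10, 0 and 9, and 6 and 0. The other 11 lists did not pass, with adjusted p between 0.066 and 0.902, and in the apoptosis list the median, mean and test differed in sign. Among these 11 lists, apoptosis genes had 3 higher and 4 lower, and p53 and Wnt targets each had 1 higher and 4 lower. DNA replication genes had 3 higher and 3 lower, and heat-shock genes 2 and 3. The interferon list had 3 lower, and its genes RIGI and USP18 changed by -0.40 and -0.47. IFIT1 was lower by at least 0.15, from a mock mean of 2.84 to 1.99, with all 3 agonist arrays at or below the 40th percentile. The calls of BAMBI, BMP4, HSPA4, MT1F, RIGI, RPL6, RPS6, RPS9 and USP18 were each lost without at least 1 array. The comparison called 5022 probe sets, 2039 higher and 2983 lower. Higher calls made up 40.6% as deposited, 43.8% after quantile normalization, 42.6% after centring on probe sets above 6 and 44.2% after cyclic loess, but 56.2% after centring on the 75th percentile.

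The 2 steps were set against each other. Of the 391 probe sets that differed between GPR39 and mock, 99 were higher in both steps against 7.79 for independent lists, 49 were lower in both against 8.39, 26 rose and then fell against 14.9, and 18 fell and then rose against 4.39. Both steps share the 3 GPR39 arrays, which cannot be split with at least 2 on each side, so part of the excess in opposite directions may come from them. The counts for independent lists take every probe set as equally likely to be called. Both steps, however, use the same spread per probe set, and exact repeats were counted. The excess in the same direction is therefore no measure of how far the steps are related. Across all tested probe sets the correlation of the log2 changes was -0.20, against -0.50 when unchanged groups sharing the GPR39 arrays were simulated. It was -0.09 with a pseudocount of 16, -0.026 with 64 and 0.10 over the 11916 named genes with 1 probe set each, against a simulated -0.50 in each case. The covariance minus the simulated one was 0.0025, but -0.00798 without mock replicate 1 and -0.000596 without agonist replicate 3, and 0.0158 over the named genes. The simulation gave all groups the same spread per probe set. The median SD over probe sets was 0.109 in the GPR39 arrays, 0.136 in mock and 0.138 in the agonist arrays. Differences from the simulated values, here and for the comparisons that share mock, therefore cannot decide whether the changes are related. Probe sets are not independent replicates. The log2 changes of GPR39 against mock and agonist against mock, which share the mock arrays, correlated at 0.59 against 0.50 simulated, with a covariance 0.0474 above the simulated one. They shared 223 higher and 116 lower calls against 15.3 and 12.6 for independent lists, which have the same limit. Part of that excess may also come from the shared arrays. FOS moved from 5.77 in mock to 5.03 in the GPR39 arrays and 6.78 in the agonist arrays. Of the 21 named genes that moved in opposite directions, ANXA3, PLEK2, NEXN and RCAN1, chosen after their values were seen, rose by 1.23, 1.18, 0.71 and 1.12 in the first step and changed by -0.64, -0.95, -1.13 and -0.54 in the next. CD70 changed by -0.96 in the latter. A test of the difference between the steps gave lower SRF and YAP targets in the agonist step (camera adjusted p = 6.10e-05, and adjusted p = 0.129 with an estimated correlation) and higher immediate-early genes (adjusted p = 1.72e-04, and adjusted p = 0.0825 with an estimated correlation), and none of the 10 lists that passed this test kept it with an estimated correlation.

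**Figure D3:**
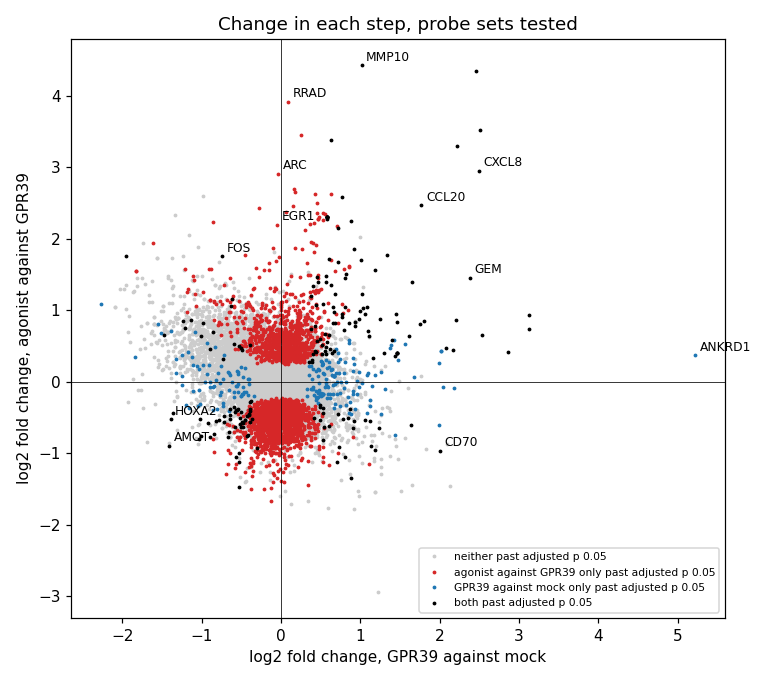
Log2 fold change of each tested probe set from mock to GPR39 (horizontal axis) and from GPR39 to agonist (vertical axis), coloured by which step passed an adjusted p of 0.05. ANKRD1 lies far along the first axis at 5.22, MMP10 and RRAD reach furthest along the second among the labelled genes at fitted values of 4.42 and 3.91, and CXCL8 is plotted high on both at 2.49 and 2.95.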

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

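A pseudocount of 16, repeated rows counted once, centring on probe sets above 6 and cyclic loess were chosen after seeing the data; the other alternatives were planned. No called gene that follows the naming rule changed direction under any alternative. Called genes named outside that rule, such as NOG in GPR39 against mock, were not followed through the alternatives. Of the called genes under the rule, 27 of 41 for GPR39 against mock, 67 of 87 for agonist against GPR39 and 89 of 100 for agonist against mock kept their call. This count leaves out the stricter thresholds, which were not applied to it. A gene that a setting did not test counted as kept. Leaving out 1 array ended 13, 20 and 9 calls. No list past the threshold had a median that turned under the 4 scaling alternatives.

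Counts for GPR39 against mock moved furthest from 391. They were 894 with a pseudocount of 64, 765 with 16, 637 with the 60th percentile filter, 663 with eBayes trend and robust, 969 with array weights, 190 with the compared arrays alone, 118 at adjusted p 0.01 and 245 at 1.5-fold or more. For agonist against GPR39 the stricter thresholds gave 1048 and 1205 against 3025, and for agonist against mock 2438 and 2208 against 5022, with 3133 for the compared arrays alone. The 2 stricter thresholds call fewer by construction; the cause of the other shifts was not tested. Leaving out each array in turn gave 108 to 1324, 1518 to 3157 and 3510 to 4969 probe sets. The highest first value came without mock replicate 1 and the lowest without GPR39 replicate 3. The replicate number as a block gave 150 and 1819 probe sets for the first 2 comparisons. Same-numbered arrays had residual correlations from -0.10 to 0.06 and their own number was the best match in 1 of 9 cases. No pairing by number was seen, but so few arrays cannot exclude it.

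With an estimated correlation 4, 3 and 6 lists passed in place of 13, 13 and 16. With fry 14, 17 and 23 passed, and every list past the threshold at the preset correlation kept its call. Unlike camera, fry does not set a list against the other genes, so it is no stricter check. Leaving out each array gave 11 to 13, 10 to 13 and 14 to 16 lists. The GPR39 probe set, near background, went from 0.0035 in agonist against GPR39 to -0.042 with quantile normalization and -0.031 with cyclic loess, and ran from -0.032 to 0.069 without 1 array. Its agonist against mock change reached 0.18 (unadjusted p = 0.047) with centring on the 75th percentile and ran from 0.075 to 0.18 without 1 array, the highest without agonist replicate 1. The correlation between the steps went from -0.20 to 0.10 with 1 probe set per named gene, -0.026 with a pseudocount of 64 and -0.09 with 16, and ran from -0.28 to -0.14 without 1 array; centring and the block cannot move it. Genes that were not called also changed sign. MT1X in agonist against mock was 0.070 with 75th percentile centring, 0.011 with array weights, 0.010 with centring on probe sets above 6 and 0.027 with cyclic loess, and -0.066 to 0.075 without 1 array. CD14 in GPR39 against mock was -0.0032 with cyclic loess and -0.020 to 0.045 without 1 array. Without 1 array MT1E ran from -0.13 to 0.37 in GPR39 against mock and from -0.065 to 0.43 in agonist against GPR39, and MT1F from -0.00128 to 0.17 in GPR39 against mock. The cause of these sign changes was not tested. Dim probe sets such as GPR39 limit what can be read from small changes.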

Other observations

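Families of genes that share a symbol stem, chosen after seeing the data, showed changes outside the fixed lists; 193 stems with at least 8 tested genes were tested with camera. In agonist against GPR39 the intraflagellar transport genes (IFT) had 6 of 17 members lower, none higher and a median of -0.34, with IFT70B at -1.13 and IFT81 at -0.75 (adjusted p = 0.00186 at the preset correlation, and adjusted p = 0.541 with an estimated correlation). The BBS genes, named for Bardet-Biedl syndrome, a disorder of cilia, had 4 of 8 lower, with BBS10 at -1.16 (adjusted p = 0.00382 at the preset correlation, and adjusted p = 0.541 with an estimated correlation). The vesicle tethering and sorting families VPS and COG had 14 of 36 and 6 of 8 lower (adjusted p = 0.00382 and 0.00394 at the preset correlation, and adjusted p = 0.541 for each with an estimated correlation), with VPS52 at -0.83. Mitochondrial ribosome genes MRPL and MRPS had 7 of 52 and 5 of 26 lower (adjusted p = 0.0314 and 0.0149 at the preset correlation, and adjusted p = 0.782 and 0.625 with an estimated correlation). Of all 11916 tested genes, 1162 had a probe set lower in this comparison and 441 had one higher, and the MRPL count is near that share. The small nucleolar RNA host genes SNHG had 3 of 8 higher, with SNHG5 at 0.88 (adjusted p = 0.00382 at the preset correlation, and adjusted p = 0.541 with an estimated correlation). No family passed with an estimated correlation in any comparison. None of these medians in agonist against GPR39 changed sign under the 4 scaling alternatives. In agonist against mock 6 of 9 HOXB genes were lower (adjusted p = 0.00848 at the preset correlation, and adjusted p = 0.531 with an estimated correlation).

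The tests of the GPR39 probe set, of a swap of arrays, of the position of mock replicate 1 and of intron RNA were chosen after the result was seen, while the normalization and scaling tests and the splits were fixed before theirs. The test of a swap took the place, after its value was seen, of one of any single array out of place, whose value was the 0.646 of mock replicate 1. For each comparison the real grouping gave 391, 3025 and 5022 probe sets. The highest of the 9 other splits of the 6 arrays gave 0 in each, and 1 of 10 splits, the real one, gave as many. With 10 splits no share under 0.05 can be reached.

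The GPR39 probe set did not rise, with a log2 change of 0.11 from mock to GPR39. The probe set may lie outside the introduced sequence, which the values cannot decide. An exchange of the labels of the whole groups was not tested. The design gives receptor and cumate together, so no biological explanation was tested.

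Mock replicate 1 correlated more with the GPR39 arrays (mean 0.984) than with the other mock arrays (mean 0.979). Over 1323 probe sets called without it under the filter of all 9 arrays, it lay at 0.646 on an axis from mock (0) to GPR39 (1), past the bound of 0.5 first set for a wrong label, while the lowest GPR39 array lay at 0.950 on an axis made without it, which argues against a swap with one of them. Split by direction, a step added after that value was seen, it lay at 0.126 (quartiles -0.01 and 0.47) over 416 probe sets higher in GPR39, and at 0.017 over the 16 of them that were at least 4-fold higher. A label holds for the whole array, so these values argue against a GPR39 array labelled as mock, although over the 907 lower probe sets it lay at 0.816, and what sets these apart stays open. A difference in signal distribution is argued against by its correlation with mock, still the lower after quantile normalization (difference -0.00417), while more intron RNA in mock replicates 2 and 3 stays undecided, since 482 microRNA and -IT genes were 0.0685 higher there by median but, relative to other genes, the rest of the group minus mock replicate 3 (-0.12) was larger in size than the rest minus mock replicate 1 (0.09).

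More probe sets fell than rose in agonist against GPR39, with 34.4% higher. An offset in scaling as the whole cause is argued against by 36.3% higher after centring on probe sets above 6 and 40.4% after centring on the 75th percentile, and a signal-dependent trend by 42.1% after cyclic loess. Part of the imbalance may follow either, given those shifts to 40.4% and 42.1%. The 482 microRNA and -IT genes were 0.10 higher by median in the same comparison, and whether this bears on the falls was not tested. The same holds for the second principal component, which separated the GPR39 arrays and mock replicate 1 from the agonist arrays. A response to the agonist stays open and untested, as does one to a lack of cumate, since the labels give cumate for the GPR39 arrays and not for the agonist arrays.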
